A study of Caenorhabditis elegans with 2 samples.

How the data were processed

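Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map where the T-box transcription factor TBX-8 lies on the genome of Caenorhabditis elegans embryos. Per the labels, the strain RW10470 carries a transgene in which TBX-8 is fused to the TY1, EGFP and 3xFLAG tags, with unc-119(+) as the marker of transformation, and the fusion protein was precipitated with an antibody against GFP. The material was whole embryos of mixed stage and mixed sex with an age of 2.5 hours, and DNA was sheared by sonication to 200 to 800 bp. There were 2 biological replicates, each with 1 technical replicate, and both belong to 1 group. The design therefore holds no comparison between conditions, and the comparisons are between replicates, between peaks and genomic background, and between classes of genes.

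Per the deposited file descriptions, the authors supplied a list of peaks and background regions called on each replicate with a control, a list called on the pooled alignments of both replicates, and a thresholded list left after the irreproducible discovery rate step, which scores how far replicates agree on the rank of regions. Coordinates are on ce11 per the file descriptions, and the sequence and annotation used here are of the same assembly (Ensembl release 115). The aligner and the peak caller are not given in the sources used here. The deposited signal value of a region was taken as the peak caller's own measure of its strength, since the sources used here do not define it. It is not scaled between lists and may grow with read number, so it was used only to rank regions and to compare regions within a list. The deposited −log10 q-value of each region was used to count regions at q below 0.05. The summit is the deposited position of highest signal within a region. The lists give no read numbers, so the depth of each replicate is unknown and no interval that needs it is given. Signal tracks and control reads were not used here.

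The thresholded list held 521 regions, here called peaks, and this number set the length of every list compared with it. Regions of the replicate lists were matched to each other and to peaks when their summits lay within 100 bp. The 521 regions with the lowest signal in the pooled list served as an internal background from the same reads and are called the lowest-ranked regions. Chance was estimated from 1000 random placements of the summits within their chromosomes, a one-sided test whose smallest possible p is 0.001. A summit counted as near a transcript start when it lay from 1000 bp upstream to 200 bp downstream of an annotated start of a protein-coding transcript, of which there were 29314. It counted as near a small RNA gene when it lay within 200 bp of a tRNA, snRNA, snoRNA or rRNA gene. Each peak was assigned to the protein-coding gene with the nearest transcript start within 2000 bp on either side, with ties to both. Permutation tests of peak height and of correlations used 100000 resamples and were two-sided, with a smallest possible p of 1e-05. Peaks per chromosome were compared with the number of protein-coding genes per chromosome by a chi-square statistic with p from 100000 multinomial draws.

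Sequence words were scored as present or absent on either strand in the 201 bp centred on each summit. They were compared by two-sided Fisher's exact tests with 2 windows per peak of the same width centred 500 bp to either side, called flanks, and with the lowest-ranked regions. All 2080 words of 6 bases, merged with their reverse complements, were tested with Benjamini-Hochberg adjustment at 0.05. The 19 gene lists covered T-box, homeobox, nuclear receptor and bHLH factors, collagens, ribosomal protein genes, histone genes, regulators and junction genes of the epidermis, body wall muscle, pharynx, intestine, neuron, germ line, Hox and posterior patterning, the Wnt and Notch pathways, mesoderm, and excretory canal and glia. Each list was compared with all other protein-coding genes on the nuclear chromosomes (19973 in all) by a two-sided Fisher's exact test, adjusted over the 19 lists. Intervals of shares are 95% Wilson intervals for peaks and sequence windows and exact Clopper-Pearson intervals for gene lists, and they cover counting error only. For a count of 0, the upper limit given is 3 counts of the total. Peaks and genes are the units of these tests, not animals, so the p-values describe these peak lists and not the spread between embryo cultures.

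The tests, the gene lists, the motifs and the processing alternatives were fixed before the data were examined, except where a later choice is named. Named genes are the protein-coding genes assigned to the 25 peaks of highest signal, up to 4 members per gene list with the highest peaks, any T-box gene with a peak, and tbx-8, tbx-9 and unc-119. Alternatives covered the rule for a shared peak, the number of top regions, the 260 highest peaks in place of all 521, the 521 highest regions of a single replicate in place of the thresholded list, the windows around starts, genes and summits, the rule that assigns genes, and the backgrounds. On simulated data, the window around transcript starts matched a direct search at 521 of 521 positions. Random peak sets were called near tRNA genes in 4 of 100 draws, and sets with planted peaks in 100 of 100. All 4 words planted at simulated summits were recovered, with 0 false calls among the 2080 words before planting. Simulated summits and their background were both random positions, so this check does not cover false calls from a difference in base composition. Random gene sets gave a call for any list in 2 of 200 draws. A list of 37 genes with part of its members planted was called in 200 of 200. These draws do not give the power for lists with a smaller share of members. Random draws of chromosomes were called in 12 of 200. Computation used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9.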

Results

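TBX-8 is a T-box transcription factor that acts redundantly with its relative TBX-9 in the morphogenesis of the C. elegans embryo. Its GFP-tagged form was mapped by ChIP-seq in 2 biological replicates of mixed-stage embryos. The replicate lists, which hold background on purpose, had 24167 regions for replicate 1 and 20865 for replicate 2, and the pooled list had 16355. The thresholded list held 521 peaks with a median signal of 101 and a range from 75.8 to 571. Regions at q below 0.05 numbered 973 in replicate 1, 819 in replicate 2 and 882 in the pooled list. All 521 peaks had the coordinates and signal of a pooled region, and they were exactly the 521 pooled regions with the highest signal. Signal values of peaks below are those of the authors' pooled list, which has no replicates of its own.

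The first question was which regions carried the highest signal and whether both replicates ranked them alike. The highest peak (II, 11960682 to 11960988, signal 571) was intergenic, within 200 bp of the snoRNA gene W03C9.9 and assigned to W03C9.1, and ranked first in each replicate, with signals of 312 and 259. The next was in an intron of M01F1.8 (III, 3499914 to 3500167, signal 496), 978 bp from a start of M01F1.9, and ranked 3 and 2 in the replicates. Peaks assigned to F55C5.17 (signal 471), K12H4.5 (signal 424) and ftt-2, which encodes a 14-3-3 protein (X, 11605758 to 11606099, signal 414), followed. The summit assigned to F55C5.17 lay inside the snoRNA gene C51F7.4, 1095 bp from the F55C5.17 start. That assigned to ftt-2 lay inside the noncoding gene F52D10.7, 507 bp from the ftt-2 start. All of the 25 highest peaks were among the 521 highest regions of both replicates. Peaks were ranked by signal on the pooled reads of both replicates, so a high rank in each replicate was favoured in advance.

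Among the 521 highest regions of each replicate, 290 (55.7%) of replicate 1 had a summit within 100 bp of one in replicate 2, against 0.118% for random placements (n = 521, p = 0.001, the smallest possible). Of the 521 peaks, 506 (97.1%) were found anywhere in the list of replicate 1 and 508 (97.5%) in that of replicate 2. With regions matched when they overlapped by at least 1 bp, 520 peaks were found in both lists, against 493 by the 100 bp rule. The 521 highest regions of both replicates included 295 peaks (56.6%), and those of neither included 29 (5.57%). Across the 493 peaks found in both lists, log2 signal correlated with Spearman's rho of 0.53 and Pearson's r of 0.66 (permutation p = 1e-05 for each, the smallest possible, 2 correlations computed). Without the 2 peaks farthest from the median of replicate 1, r was 0.64. These are correlations across regions of 2 libraries, and regions are not independent replicates. The authors chose the peaks from both replicates, so the p-values do not test agreement outside this list. For the same reason, the counts of peaks found in each replicate are not an independent test of agreement.

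**Figure D1:**
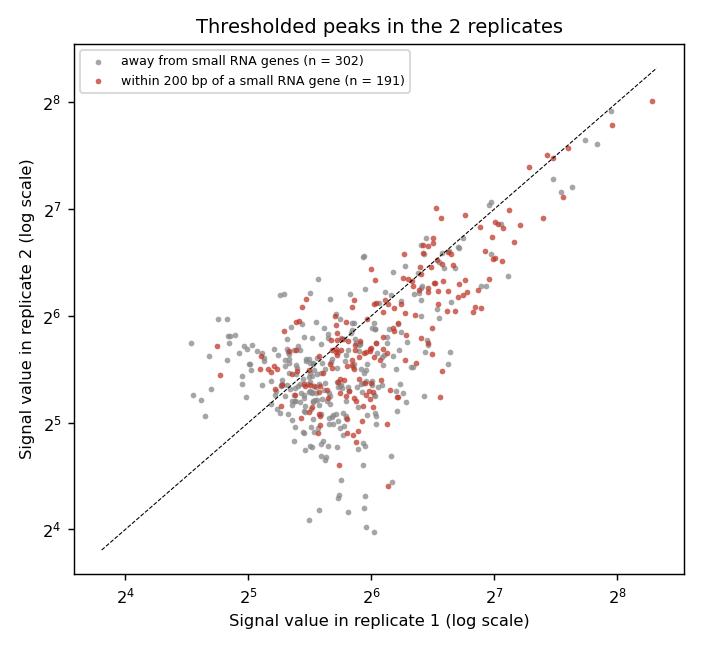
Signal value of each thresholded peak found in both replicate lists (n = 493), with replicate 1 on the horizontal and replicate 2 on the vertical axis, both on a log scale. Red points lie within 200 bp of a tRNA, snRNA, snoRNA or rRNA gene, grey points lie elsewhere, and the dashed line marks equal values for orientation only, since signal is not scaled between lists. Peaks higher in one replicate tend to be higher in the other, with Pearson's r of 0.66 over all points.

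The next question was which kinds of genes the peaks lie at. Genes for small structural RNAs carried 195 of the 521 peaks (37.4%) within 200 bp, 68.4 times the share of random placements (0.547%). tRNA genes accounted for 129 peaks (24.8% against 0.291% at random, 85.1-fold), snoRNA genes for 53 (10.2%, 55.5-fold) and snRNA genes, whose products act in splicing, for 14 (2.69%, 45.6-fold), each with the smallest possible p of 0.001. Counted by gene, 139 of 612 tRNA genes (22.7%), 51 of 346 snoRNA genes (14.7%) and 13 of 129 snRNA genes (10.1%) had a peak within 200 bp. The lowest-ranked regions lay near a tRNA gene in 0.576% of cases, near a snoRNA gene in 0.384% and near any of these genes in 1.34% (two-sided Fisher's exact test for any of them, odds ratio 43.9, adjusted p = 7.07e-57 over 13 classes). Of the 20 rRNA genes, none had a peak, but 20 genes are too few to tell their share from those of snoRNA and snRNA genes. Genes of the annotation's general class of noncoding RNA had 172 peaks within 200 bp (33.01%, 9.08-fold over random, against 7.10% of the lowest-ranked regions, Fisher's exact test, adjusted p = 4.09e-26). Of these peaks, 113 also lay near a small RNA gene, and the other 59 were 18.1% of the peaks away from small RNA genes. The test of tRNA genes against random placements was fixed before the data were examined. The other tests of gene classes in this paragraph were not among those fixed beforehand.

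Of the 25 highest peaks, 16 lay within 200 bp of a small RNA gene, and 12 of those were near a snoRNA gene. These included the peaks assigned to str-56 and sre-23, which belong to chemoreceptor families (signals 356 for both), Y43F8C.7 (signal 291), T02E1.2 (signal 261), the MAP kinase gene mpk-2 (signal 249), madf-11 (signal 248) and wrt-3 (signal 236). Peaks near tRNA genes were assigned to C04A11.5 (X, signal 324) and to cye-1, which encodes cyclin E (I, 6781562 to 6782021, in an intron, signal 247). Among the highest peaks away from small RNA genes were those of gst-11 (X, signal 331), tasp-1 (III, 54 bp from its start, signal 259), T13C5.6 (X, signal 258) and rpl-3, which encodes a ribosomal protein (III, 3867471 to 3867665, signal 250). Median signal was 118 for peaks near small RNA genes and 92.2 for the others, a log2 difference of 0.36 (permutation p = 1e-05, the smallest possible, a test added after the data were seen).

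**Figure D2:**
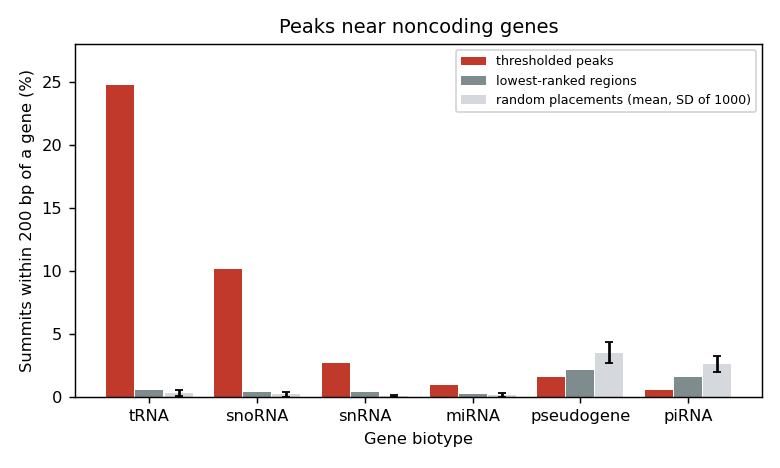
Share of summits within 200 bp of a gene of each noncoding biotype, in percent, for the 521 thresholded peaks, the 521 lowest-ranked regions and random placements (mean, with bars for the SD over 1000 placements). tRNA genes reach 24.8% and snoRNA genes 10.2% of peaks, against under 1% in either background.

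Protein-coding promoters formed another large class of locations. Of the 521 summits, 257 (49.3%) lay near a protein-coding transcript start, against 25.4% ± 1.90 (SD over 1000 placements) at random (p = 0.001) and 29.6% of the lowest-ranked regions (two-sided Fisher's exact test, odds ratio 2.32, p = 8.53e-11). Without peaks near small RNA genes, the share was 63.2% of 326, a set chosen after the data were seen. By annotation, 256 summits (49.1%) were intergenic, 115 (22.1%) intronic, 90 (17.3%) inside a small RNA gene, 35 (6.72%) inside another noncoding gene, 13 (2.50%) in a coding exon, 8 in a 5′ UTR and 4 in a 3′ UTR. Coding exons held 24.8% and small RNA genes 0.384% of the lowest-ranked regions. Peaks near a transcript start had a median signal of 99.6 and the other peaks one of 103, and the log2 difference of -0.04 was not distinguished from 0 (permutation p = 0.4). It changed sign without replicate 1 (0.029, permutation p = 0.57) and away from small RNA genes (0.10, permutation p = 0.069).

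The gene lists asked whether genes of a given tissue or pathway carried peaks more often than other genes. Ribosomal protein genes and histone genes did. In all, 372 of 19973 protein-coding genes (1.86%) had an assigned peak. Ribosomal protein genes had one in 7 of 76 cases (9.21%, interval 3.78% to 18.1%, odds ratio 5.43, Fisher's exact test, adjusted p = 0.0101), including rpl-3 (signal 250), rpl-15 (IV, signal 224), rpl-35 (III, signal 169) and rpl-12 (IV, signal 98.3). Histone genes had one in 6 of 72 cases (8.33%, interval 3.12% to 17.3%, odds ratio 4.85, Fisher's exact test, adjusted p = 0.0212), including his-67 (I, 9988699 to 9989158, signal 221), his-32 (IV, signal 127), his-37 (V, signal 108) and his-60 (IV, signal 85.7). All 13 of these genes had a peak more than 200 bp from any small RNA gene. Among the named histone genes, the summits at his-32 and his-60 lay in coding exons and those at his-67 and his-37 were intergenic. For the his-60 peak, no region of replicate 2 had a summit within 100 bp, which does not show that signal was absent there. Whether reads shared between gene copies add to the peaks at histone genes was not tested. When every gene with a start within 2000 bp of a peak was counted, the shares were 21.1% for ribosomal protein genes (2.97% of other genes) and 23.6% for histone genes (2.96% of other genes). Under this rule a single peak can count for several neighbouring genes, so these genes are not independent and the higher shares are not stronger evidence. Among the 260 highest peaks neither list passed Fisher's exact test (adjusted p = 0.35 for both), with odds ratios of 4.29 for ribosomal protein genes and 4.53 for histone genes. The histone list also did not pass without replicate 2 (odds ratio 4.01, Fisher's exact test, adjusted p = 0.101), in peaks high in both replicates (odds ratio 3.93, adjusted p = 0.289) or with starts within 5 kb (odds ratio 3.83, adjusted p = 0.064). It passed in 5 of 9 alternatives and the ribosomal list in 8 of 9.

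No other list passed the adjusted threshold. Hox and posterior patterning genes had a peak in 2 of 16 cases (12.5%, interval 1.55% to 38.3%, Fisher's exact p = 0.0349, adjusted p = 0.221): tlp-1, a zinc finger gene of tail development (IV, 74 bp from the start, signal 82.1), and ceh-20, which encodes a Hox cofactor of the PBX family (III, signal 76.4). This list had 1 of 16 without replicate 1 and 0 of 16 without replicate 2, in the 260 highest peaks and in peaks high in both replicates. Collagen genes had one in 6 of 175 cases (3.43%, Fisher's exact test, adjusted p = 0.694), and 4 of them, col-94 (signal 231), col-181 (signal 214), col-85 (signal 194) and col-185, had their peak beside a tRNA or snRNA gene. Nuclear receptor genes had one in 3 of 269 cases (nhr-255, signal 123, beside a tRNA gene; nhr-1, signal 90.6; nhr-47, signal 79.9), and homeobox genes in 2 of 63 (ceh-39, signal 78.8, and ceh-20), with adjusted p = 0.953 by Fisher's exact test for both lists. Without replicate 1 these counts were 1 of 269 and 1 of 63, and without replicate 2 the homeobox count was 0 of 63. The 5 other lists with any member had 1 each: lag-1, the DNA-binding effector of Notch signalling (signal 122, 1 of 19), cam-1, which encodes a Ror receptor kinase (signal 102, 1 of 28 in the Wnt list), egl-17, which encodes a fibroblast growth factor (signal 196, beside a tRNA gene, 1 of 23 in the mesoderm list), spc-1, which encodes alpha spectrin (signal 84.3, 1 of 37 epidermal junction genes), and unc-97 (signal 76.6, 1 of 45 body wall muscle genes). Their adjusted p-values were 0.953 or above. Some of these peaks ranked low in a replicate: in replicate 2 unc-97 ranked 6245 and nhr-1 ranked 1797. In replicate 1 ceh-20 ranked 1640. For spc-1, no region of replicate 2 had a summit within 100 bp, which does not show that signal was weak there. The Wnt list had 3 of 28 without replicate 1 (Fisher's exact test, adjusted p = 0.0983) and 2 of 28 without replicate 2, and the body wall muscle list 0 of 45 without replicate 1. No peak was assigned to a member of the lists for T-box factors (0 of 21), bHLH factors (0 of 25), epidermal regulators (0 of 20), pharynx (0 of 27), intestine (0 of 33), neurons (0 of 59), germ line (0 of 37) or excretory canal and glia (0 of 20). Without replicate 1 the neuron list had 2 of 59 and the germ line list 1 of 37, and with starts within 5 kb the neuron list had 3 of 59. Counts of 0 allow shares of up to 5.08% for the neuron list and up to 15% for the smallest lists, all above the 1.86% of all genes, so a lower share than in other genes was not detectable.

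Chromosomes carried peaks unevenly. X held 126 peaks (24.2%, interval 20.7% to 28.0%), 1.77 times the number expected from its protein-coding genes, and III held 109 (1.58 times), whereas V held 58 (0.445 times). Counts were 77 on I (1.03 times), 81 on II (0.900 times) and 70 on IV (0.818 times). The chi-square statistic was 109 (p = 1e-05, the smallest possible). Peaks near tRNA genes lay on X in 66 of 129 cases (51.2%), and 276 of 612 tRNA genes (45.1%) are on X. Away from small RNA genes, 60 of 326 peaks (18.4%, interval 14.6% to 22.97%) were on X, III held 83 (1.93 times) and V held 35 (0.429 times). The lowest-ranked regions also departed from gene number, with 1.24 times on X, 1.29 times on III and 0.652 times on V. Expected from chromosome length instead, the ratio on X was 1.37.

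**Figure D3:**
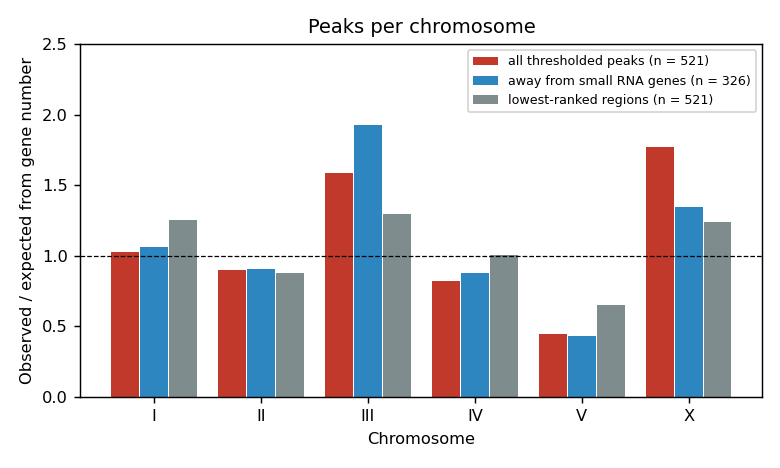
Observed number of regions per chromosome divided by the number expected from protein-coding genes, for all 521 thresholded peaks, the 326 peaks away from small RNA genes and the 521 lowest-ranked regions, with the dashed line at a ratio of 1. The X ratio is 1.77 for all peaks and 1.35 away from small RNA genes, and V lies below 1 in all 3 sets.

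The T-box core GGTGTG was tested because T-box proteins bind sites of the form AGGTGTGA. It was present at 50 of 521 summits (9.60%, interval 7.36% to 12.4%), against 4.13% of flanks (two-sided Fisher's exact test, odds ratio 2.47, p = 3.46e-05) and 6.33% of the lowest-ranked regions (odds ratio 1.57, p = 0.0666). The flanks and the lowest-ranked regions were both backgrounds fixed beforehand for the core. Against the lowest-ranked regions, the difference did not pass the threshold. It did in the 260 highest peaks (10.8%, Fisher's exact p = 0.0339) and, in a set chosen after the data were seen, away from small RNA genes (10.7%, p = 0.0268), though not after adjustment over the 8 word classes (adjusted p = 0.0535). The full site AGGTGTGA was at 5 summits (0.960%, against 0.576% of the lowest-ranked regions, Fisher's exact p = 0.726) and in 1 of 1042 flanks (0.096%, odds ratio 10.1, Fisher's exact p = 0.0176). The direction turned for GGTGTGA, at 1.73% of summits against 2.30% of the lowest-ranked regions (odds ratio 0.746, Fisher's exact p = 0.66). Summit windows were richer in G and C, with a median of 46.8% against 36.3% in flanks and 37.8% in the lowest-ranked regions. Random positions matched on GC content carried the core in 7.50% ± 1.18 of cases (SD over 1000 draws, n = 521 summits, one-sided p = 0.052). Among the 15 words of the same base composition, the core ranked 6 by odds ratio against flanks and 9 against the lowest-ranked regions. Median signal was 107 with the core and 101 without it (permutation p = 0.35). The GC-matched comparison of the core, its ranking among words and this test of signal were not among the tests fixed beforehand.

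GAGA and SP1-type words were more frequent at summits than in both backgrounds and at GC-matched positions. The GAGA word GAGAGA was at 32.2% of summits against 11.04% of flanks (odds ratio 3.84, Fisher's exact test, adjusted p = 2.41e-22 over 8 classes) and 13.1% of the lowest-ranked regions (adjusted p = 9.60e-13), and the SP1-type word GGGCGG at 14.6% against 2.88% of flanks (odds ratio 5.76, adjusted p = 2.58e-16) and 5.76% of the lowest-ranked regions (adjusted p = 1.17e-05). GATA factor words were less frequent at summits than in flanks (13.6% against 27.6%, odds ratio 0.413, Fisher's exact test, adjusted p = 5.46e-10) and in the lowest-ranked regions (23.4%, adjusted p = 0.000165). Homeodomain words were less frequent than in flanks (8.83% against 17.7%, odds ratio 0.452, Fisher's exact test, adjusted p = 4.55e-06), but the difference from the lowest-ranked regions (13.1%) did not pass (adjusted p = 0.0736). HLH-1 type E-boxes (5.76% against 4.13%), forkhead words (17.9% against 15.5%) and the E-box CACGTG (4.03% against 4.41%) did not differ from flanks, with adjusted p of 0.216, 0.281 and 0.792. Against random positions matched on GC content, a comparison added after the data were seen (1000 draws, n = 521, smallest possible two-sided p of 0.002), GAGA words (14.95% at matched positions) and SP1-type words (7.53%) stayed more frequent at summits (p = 0.002 for each, unadjusted), and forkhead words were more frequent too (12.1%, p = 0.002). GATA words (16.5%, p = 0.098, n = 521), homeodomain words (7.27%, p = 0.17), HLH-1 type E-boxes (7.04%, p = 0.27) and CACGTG (5.42%, p = 0.17) were not distinguished from matched positions. Of all 2080 words of 6 bases, 539 were enriched and 384 depleted at summits, and 1026 had an unadjusted p under 0.05. GCGCGC led the list (15.9% against 1.44%, odds ratio 13.0, Fisher's exact test, adjusted p = 4.75e-24). CGAACC (22.6% against 4.41%, odds ratio 6.34) and GTTCGA (26.7% against 7.97%, odds ratio 4.20) belong to the B box, the internal promoter element of tRNA genes. GC-matched positions carried these 3 words in 3.47%, 5.91% and 9.15% of cases (p = 0.002 for each, n = 521). Apart from these words and the word classes above, no word was set against such positions. The positions were not matched on distance to a transcript start, so words common at promoters were not told apart from words particular to these peaks. Away from small RNA genes, CGAACC and GTTCGA were no longer enriched (5.21% against 3.22% and 7.06% in both, Fisher's exact test, adjusted p = 0.301 and 1), while GCGCGC was at 21.2% against 1.38% and GAGAGA at 34.4% against 11.5%.

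**Figure D4:**
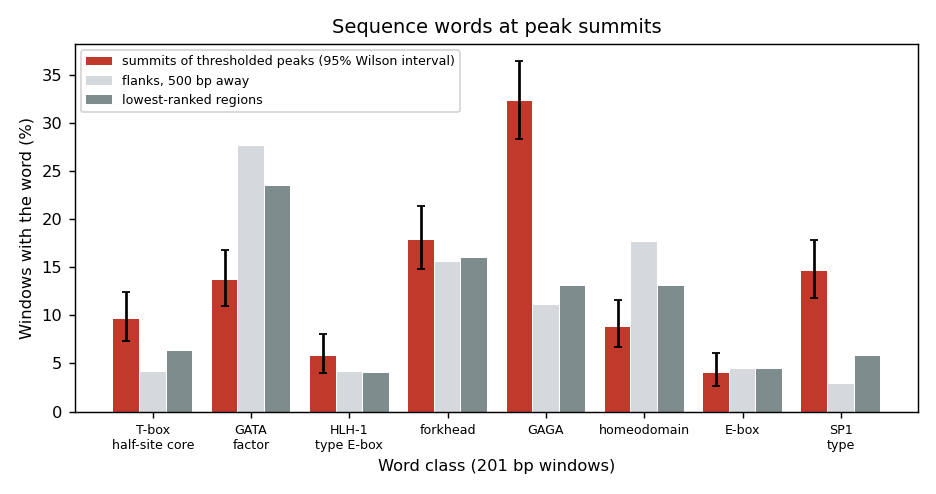
Share of 201 bp windows with each class of sequence word, in percent, at the summits of the 521 thresholded peaks (bars for 95% Wilson intervals), in their flanks and in the lowest-ranked regions. GAGA and SP1-type words are more frequent at summits than in either background, GATA words are less frequent, and the T-box core is at 9.60% of summits against 4.13% and 6.33%.

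The tagged gene and the transgene marker were examined because extra copies can change read numbers there. tbx-8 (III, 10347349 to 10349740, + strand) had no region within 20000 bp of its start in the pooled list or in either replicate list, whereas windows on random protein-coding genes held a median of 5 pooled regions, which placed tbx-8 at percentile 1.4. Its neighbour tbx-9 (III, 10340006 to 10341858, - strand) lay in the same gap, which spanned 54.5 kb in the pooled list, 44.6 kb in replicate 1 and 57.0 kb in replicate 2. The nearest peak was 60.2 kb from the start of tbx-8 and 65.7 kb from that of tbx-9. unc-119 (III, 10902641 to 10908935), which is needed for normal movement and marks the transgene, had no peak but 8 pooled regions within 20000 bp (percentile 73.2), the nearest 421 bp from its start with a signal of 39.5. Within 10000 bp and 50000 bp of tbx-8, the percentile was 5.85 and 38.4. Windows on random genes were also empty in the pooled list in 2.8% of cases at 20000 bp and 11.7% at 10000 bp. The percentiles of 1.4 and 5.85 lie below these shares and do not give the share of windows as empty as that of tbx-8.

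**Figure D5:**
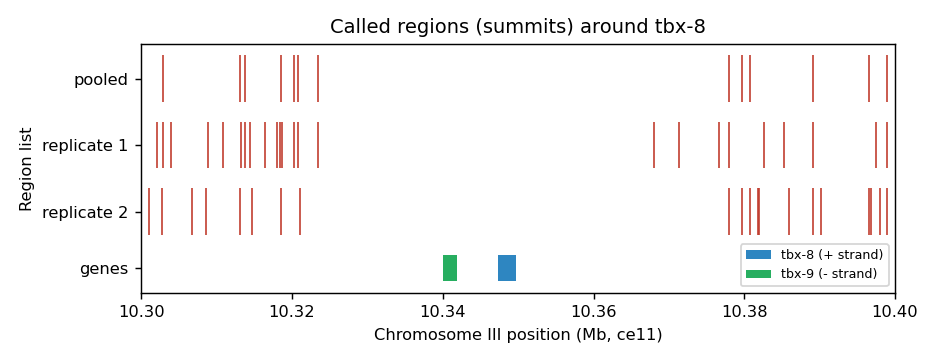
Map of chromosome III around tbx-8 (ce11, position in Mb) with the summit of every called region in the pooled and replicate lists as a vertical line and tbx-8 and tbx-9 as boxes to scale. No list has a summit within 20000 bp of the start of tbx-8.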

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

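Peak sets away from small RNA genes and sets high in both replicates were chosen after seeing the data; the other alternatives were fixed before. Of 62 alternative values for 11 results, 48 kept their direction and their side of the threshold (counts within 1.5 times), and 6 results did so under all alternatives run. Exceptions were as follows, and the cause was not tested unless given. The T-box core passed against the lowest-ranked regions at 10.8% in the 260 highest peaks and at 10.7% away from small RNA genes (unadjusted p, 0.0535 when adjusted over 8 word classes), over 10 alternatives p ran from 0.0268 to 0.726, and with GGTGTGA the direction turned (1.73% of summits). The difference in peak height near starts, not past the threshold, turned to 0.10 away from small RNA genes. Leaving out a replicate gave it a range from -0.045 (without replicate 2) to 0.029 (without replicate 1). Enriched words, 539 in the report, numbered 332 away from small RNA genes, 347 against the lowest-ranked regions and 871 with words of 7 bases, of which more were tested (8192). Gene lists that passed, 2 in the report, numbered 0 in the 260 highest peaks (odds ratios 4.29 for ribosomal protein and 4.53 for histone genes, against 5.43 and 4.85), 1 in peaks high in both replicates and 1 with starts within a wider window of 5 kb, and leaving out a replicate gave 1 (without replicate 2) to 2 (without replicate 1). Without replicate 2 the histone genes had a share of 6.94%, an odds ratio of 4.01 and an adjusted p of 0.101. Their odds ratio was 3.93 in peaks high in both replicates and 3.83 with starts within 5 kb. Histone genes passed in 5 of 9 alternatives (adjusted p from 6.85e-10 to 0.35) and ribosomal protein genes in 8 of 9 (8.07e-09 to 0.35). The lowest value of each came from counting every start, where a single peak can count for several neighbouring genes that the test treats as independent. The percentile of tbx-8 was 5.85 within 10000 bp and 38.4 within 50000 bp, as the wider window reaches past the gap. For single gene lists, 141 of 171 alternative values kept direction and side, 5 lost the call, and 25, none of them past the threshold, turned direction. The homeobox, epidermal junction, body wall muscle and Hox lists fell to 0% in the 260 highest peaks and in peaks high in both replicates. Collagens were at 1.14% and the mesoderm list at 0% away from small RNA genes, and the muscle, Wnt and Notch lists at 0% with starts within 1 kb. The muscle list was at 2.22% and neurons at 5.08% with starts within 5 kb, and the muscle list at 2.22% with every start counted. The junction, muscle and Wnt lists were at 4.55%, 4.76% and 7.69% against genes of a wider background, the 8177 lowest-ranked regions of the pooled list. Leaving out a replicate gave 0% to 1.59% (homeobox), 0% to 2.22% (muscle), 0% to 3.39% (neurons), 0% to 2.70% (germ line) and 0% to 6.25% (Hox). No paired analysis was possible because there is only 1 group. The lists give no read numbers, so what sequencing depth limits could not be measured, and small or zero counts limit the gene lists.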

Other observations

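The tests of shared copies, of ribosomal protein genes as a class, of X, of empty windows and of unc-119 were chosen after the result was seen, as were the counts for microRNA genes, tRNA types and gene names, whereas those of GC content at small RNA genes and of repeated sequence were set out before. The tests of spliced leader and piRNA genes were not among those fixed beforehand.

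MicroRNA genes of a single family stood among the highest peaks. Peaks 9 and 10 by signal lay within 200 bp of mir-52 (IV, 14033860 to 14034194, signal 348) and of mir-51 (IV, 11026045 to 11026314, signal 334), which belong to the mir-51 family, and a second summit, called as a peak of signal 107 over almost the same interval, lay at mir-52. Another peak lay in the cluster of mir-35 to mir-38, whose products act in the embryo (II, 11537540 to 11537999, signal 90.9), and one at mir-4936 (III, signal 103). Counting both summits at mir-52, 5 peaks lay near a microRNA gene (0.960% against 0.122% at random, p = 0.001), a share that was not distinguished from the 0.192% of the lowest-ranked regions (Fisher's exact test, adjusted p = 0.324). Genes of the SL2 type of spliced leader RNA, which is joined to transcripts of operons, had 5 peaks: sls-2.2 (signal 205), sls-2.4 (177), sls-2.1 (175), sls-2.8 (109) and sls-2.9 (98.1). They are among the 14 peaks near snRNA genes, and against 0 of the lowest-ranked regions the difference did not pass (Fisher's exact test, adjusted p = 0.115). Genes for piRNAs lay near fewer peaks than random placements (0.576% against 2.61%, n = 521, lower-tail p = 0.002), a share that was not distinguished from the 1.54% of the lowest-ranked regions (Fisher's exact test, adjusted p = 0.324).

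tRNA genes of 20 of the 21 types by amino acid carried peaks, all except the single gene for selenocysteine. Apart from it, the share with a peak ran from 1 of 27 for glutamine to 12 of 34 for alanine, and the differences over 21 types were not larger than chance (permutation p = 0.85, 605 genes matched to a type). On X, 71 of 276 tRNA genes had a peak (25.7%) and on the autosomes 68 of 336 (20.2%), which did not differ (Fisher's exact test, p = 0.121). A scan of 175 classes of gene names found 0 that passed the adjustment by Fisher's exact test and 10 at an unadjusted p under 0.05. The rpl class led with 5 of 47, and it includes rpl-7A, a name that the ribosomal list had missed. The his class followed with 6 of 72, both with an adjusted p of 0.195. The lin class had lin-28, lin-42, lin-59 and lin-66 among its members with a peak (Fisher's exact test, adjusted p = 0.656).

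The excess at small RNA genes was weighed against technical explanations. GC content as the whole cause is argued against, since peaks lay near these genes 32.9 times as often as GC-matched positions. Reads shared between gene copies are argued against for snoRNA genes, because peaks lay near those without a 36-base word elsewhere in the genome 61.1 times as often as random placements (48 of 304 such genes had one). For snRNA genes that explanation stays open, since only 2 of 26 unshared genes had a peak (25-fold), too few to decide. For tRNA genes it also stays open, since 0 of 25 unshared (which allows up to 12%) and 139 of 587 shared genes had a peak (Fisher's exact test, p = 0.00242), though unshared copies may also be inactive. Signal at busily transcribed genes that does not depend on TBX-8 also stays open as a candidate explanation, in line with the odds ratio of 5.43 for ribosomal protein genes, and binding of TBX-8 itself was not tested, since no untagged strain was analysed here.

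The excess on X may have 2 parts. Small RNA genes as the whole cause stay open: 18.4% of peaks away from them were on X, and the interval of 14.6% to 22.97% lies above the 13.7% of protein-coding genes but includes the 16.9% of the lowest-ranked regions and the 17.7% of the genome's length. This remainder was not distinguished from the lowest-ranked regions (odds ratio 1.11, Fisher's exact test, p = 0.578), in line with gene number being too low an expectation for any called region. No biological explanation was tested.

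The gap at tbx-8 and tbx-9 ranked 60 among 16349 gaps in the pooled list, 27 among 24161 in replicate 1 and 15 among 20859 in replicate 2. Repeated sequence is argued against, since the share of soft-masked bases was at percentile 62.3. A chance gap stays open: windows reaching 20000 bp to either side of random genes were empty in at most 2.8% of cases in any of the 3 lists, but windows reaching 10000 bp were empty in 3.2% (replicate 1) to 11.7% (pooled list), and the lists are not independent. Extra transgene copies that raise reads in the control could leave such a gap and cannot be told apart from other causes, since control reads were not used here. Regions around unc-119, at percentile 73.2, did not decide it, as the length of the marker's copy is not given in the labels.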
